A study of Mus musculus with 11 samples.

How the data were processed

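Memory B cells of wild type and Zbtb32-/- donors, sorted from the spleens of recipients 7 days after a boost with NP-CGG, were measured on 11 arrays, 6 and 5 per genotype. Per the labels' protocols, donor cells were told from recipient cells by their form of CD45 and gated as CD19, CD80, CCR6 and NP positive and as IgD, IgM, CD11b, Ly6g and CD117 negative, RNA was taken up with a column kit for small samples, and label was added with the Affymetrix WT Pico and Encore Biotin kits. The deposited values are log2 signals per probe set, made with Affymetrix Expression Console and RMA (background correction, quantile normalization between arrays and summary of probes per probe set), per the submitters' processing notes. Versions of both tools, scan dates and batches are not given in the sources used here, and the log2 scale was read from the range of the values, 2.30 to 14.38. RMA shrinks differences of dim probe sets and brings the distributions of the arrays closer, so a shift shared by most genes could be hidden. The deposited values still differed in spread between arrays. Their SD was 1.88 in wild type replicate 6 and 2.13 in wild type replicate 1, with upper quartiles of 7.63 and 8.01. Array medians ran from 6.34 to 6.52. Arrays give no read depth; their number limits the precision, and the median standard error of a difference between genotypes was 0.16 log2 units.

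Probe sets were named through the platform annotation supplied with the table. Of 35556 probe sets 21789 had 1 gene symbol, 1621 had several and were not named, and 12146 were not listed in that annotation and stayed unnamed. Of the single-symbol probe sets 21698 were matched by gene identifier to a reference gene table of mouse assembly GRCm38.p6, which changed 0 symbols. Where a symbol had several probe sets, as 999 genes did, the one with the highest mean over all arrays was kept, leaving 19938 genes. No filter on dim genes was set. The array's genome build is not given in the sources used here, so no coordinates are given.

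Zbtb32-/- cells were compared with wild type cells in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with default settings, two-sided), with Benjamini-Hochberg adjustment over all genes and an adjusted p under 0.05 as the threshold. Differences are Zbtb32-/- minus wild type on the log2 scale. Single genes were also set against all 462 splits of the arrays into 6 and 5 in a two-sided exact permutation test, whose smallest possible p is 0.00216. The series text calls the samples biological replicates, and nothing states how many donors or recipients stood behind each array. Samples of both genotypes share numbers 1 to 5; nothing in the labels pairs them and no block was used in the reported comparison.

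Before the data were examined, 31 gene lists holding 799 entries were fixed, of which 742 were measured, 14 of them through an older symbol. They cover mitosis, DNA replication and S phase, cell cycle inhibitors, respiratory chain and ATP synthase, mitochondrial ribosome, mitochondrial biogenesis and import, TCA cycle, fatty acid oxidation, glycolysis, ribosome biogenesis and Myc targets, plasma cell programme, unfolded protein response, germinal centre, memory, atypical and general B cell genes, MHC class II presentation, immediate early response, NF-kB targets, interferon response, apoptosis regulators, immunoglobulin isotypes, genes next to Zbtb32, and markers of T cells, NK cells, macrophages and monocytes, neutrophils, mast cells and basophils, dendritic cells, erythroid cells and platelets. Of the marker lists, Tcf4, Ly6d, Tfrc, Bst2, Il2rb and Cd5 are also expressed by B cells, and other members may be as well. Lists were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over the lists, and again with the correlation estimated per list, with fry, and with the exact permutation test of list means. Most constant region genes of antibodies, Cd19, Cd38 and Lyn lay on probe sets with several symbols or no listed name and were not analysed here.

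Genes named in the text followed a rule fixed at the same time: Zbtb32; the 12 genes of largest difference per direction among those past the threshold, filled up with those of smallest p where fewer passed, leaving out predicted genes, antibody and T cell receptor segments and histone cluster genes; the 4 members of smallest p in each list, of which the text names some; the genes of the sort gate; and all measured isotype genes. Genes named outside this rule were chosen after their values were seen, and are Atp13a1 and Fntb in the report and Cd22, Cr2, Lyz2, Prdm1, Sdc1 and Spic in the closing section. The 10 B cell genes silenced in plasma cells, taken later from the B cell identity list by their known biology, were Bank1, Blk, Cd22, Cd72, Cr2, Ebf1, Fcer2a, Ms4a1, Pax5 and Spib. The test was checked on simulated data for this comparison, with 19938 genes on 11 arrays. It recovered 68.7% of 67 genes changed by 1 log2 unit, 92.5% of 67 changed by 2 and 100% of 66 changed by 3, with 4 false calls. The simulated noise was independent between genes, while the real arrays differed along axes shared by many genes. These rates therefore do not give the power of the real comparison, in which Zbtb32 at -2.21 did not pass.

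Alternatives fixed beforehand were repeated quantile normalization, median centring, a filter on dim genes, the mean of a gene's probe sets, every probe set, trended robust moderation, array weights, the replicate number as a block, leaving out each array, a threshold of 0.1, an unmoderated test, other set tests, lists without genes whose probe sets disagree and neighbours of Zbtb32 taken from the reference table. Leaving out Zbtb32-/- replicates 4 and 5 together was added after the data had been seen. Figures were drawn with matplotlib 3.10.9.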

Results

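Gene expression was measured on microarrays in mouse memory B cells specific for the hapten NP, a small molecule that raises antibodies when coupled to the carrier protein CGG. Splenocytes of immunised donors, either wild type or lacking Zbtb32, a zinc finger transcriptional repressor, were moved into recipients carrying the other form of the CD45 surface marker, and the recipients were boosted with NP-CGG. Donor memory B cells were sorted from the spleen 7 days after the boost. The 11 arrays fell into 6 of wild type cells and 5 of Zbtb32-/- cells, described in the series as biological replicates, each array with 1 value for each of 35556 probe sets. Median signals lay between 6.34 and 6.52 log2 units, pairs of arrays correlated at 0.887 to 0.969, and no pair held identical values. The number of arrays limits the precision.

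The comparison of the genotypes asks what Zbtb32 controls in memory B cells during a recall response, and its targeted gene was examined before the rest. Zbtb32 signal averaged 9.71 ± 0.88 (SD, n = 6) in wild type cells and 7.50 ± 0.36 (SD, n = 5) in Zbtb32-/- cells, a difference of -2.21 ± 0.38 (SE) log2 units, or 4.63-fold lower. It was lower in 5 of 5 Zbtb32-/- arrays, with no overlap between the genotypes (two-sided exact permutation p = 0.00433). Wild type replicates 2 to 6 lay between 9.25 and 10.61, wild type replicate 1 at 8.28, and the Zbtb32-/- arrays between 7.03 and 7.88. With all genes tested together the limma adjusted p was 0.996, and without wild type replicate 1 it was 0.0345 with a difference of -2.50. Which exons were deleted is not given in the sources used here, so whether the probe set lies within the deleted part is unknown.

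**Figure D1:**
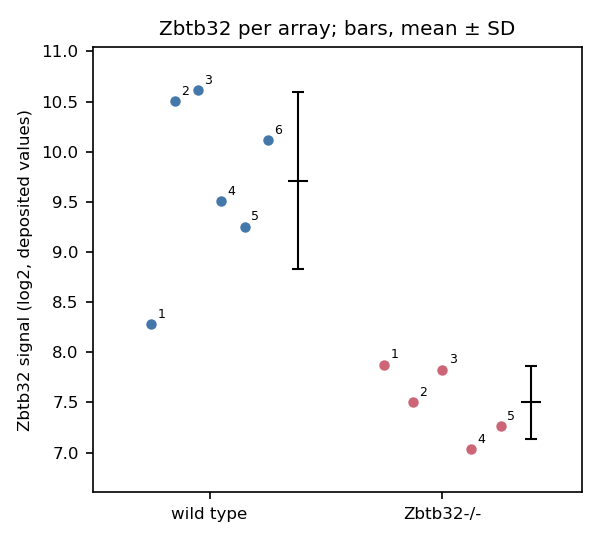
Zbtb32 signal in log2 units (vertical axis) in 6 wild type and 5 Zbtb32-/- arrays (horizontal axis); each point is 1 array with its replicate number and bars give mean ± SD. The Zbtb32-/- arrays lie between 7.03 and 7.88, all below the wild type arrays, whose lowest is replicate 1 at 8.28.

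Across 19938 genes, no difference between Zbtb32-/- and wild type memory B cells passed, given the spread among arrays. This does not show that expression was alike, since Zbtb32 itself, at -2.21 log2 units, did not pass either. No gene reached a limma adjusted p under 0.05, and the smallest adjusted p was 0.996. At an unadjusted p under 0.05 there were 673 genes, 418 higher and 255 lower in Zbtb32-/- cells, against 997 expected by chance. The genotypes did not overlap for 24 genes, 0.12% of those tested, where chance gives 0.433%. Without wild type replicate 1 the count past the adjusted threshold was 3, made up of Zbtb32, Atp13a1 at 0.78 and Fntb at 0.89, and 1892 genes had an unadjusted p under 0.05. Zbtb32-/- replicates 4 and 5 both lay below or both above the other 9 arrays in 1932 genes, where chance gives 3.64% of the 19938. The median over 55 pairs of arrays was 454 genes. This pair ranked 4, and wild type replicate 1 with Zbtb32-/- replicate 2 had the most, 2825. Without Zbtb32-/- replicates 4 and 5 no gene passed and 547 had an unadjusted p under 0.05.

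The genes of smallest p, given as values that did not pass the adjusted test, came from many functions. On the higher side in Zbtb32-/- cells were Vopp1 at 1.48 ± 0.27 (SE, log2), Tmem104 at 1.51 ± 0.34, Slc39a10, a zinc importer, at 1.23 ± 0.31, Lclat1, a cardiolipin acyltransferase, at 1.13 ± 0.26, and Lgmn, the lysosomal protease legumain, at 0.89 ± 0.19. Igha, the constant region of the IgA heavy chain, had the largest difference among the 24 genes named this way, 3.00 ± 0.79, from 8.44 ± 0.62 (SD, n = 6) to 11.44 ± 2.11 (SD, n = 5). Actn1 at 1.05, Plin2, a lipid droplet coat protein, at 0.95, Shkbp1 at 0.92, Slc43a2 at 0.74, Hgh1 at 0.61 and Gxylt1 at 0.55 completed that side. On the lower side, besides Zbtb32, Zfp961 stood at -1.06 ± 0.21, Mr1, which presents vitamin B metabolites to T cells, at -0.92 ± 0.26, Ubxn2b at -0.89 ± 0.25, Polr3f, a subunit of RNA polymerase III, at -0.87 ± 0.21, and Rpp30, a subunit of RNase P, at -0.85 ± 0.24. The rest were Pramel20 at -0.76, Auh, a mitochondrial enzyme of leucine breakdown, at -0.75, Sucla2, a subunit of the TCA cycle enzyme succinyl-CoA synthetase, at -0.59, Rbfa at -0.41, Spryd7 at -0.39 and Izumo3 at -0.31. All of the higher genes exceeded the wild type mean in 5 of 5 Zbtb32-/- arrays. All of the lower genes lay below that mean in 5 of 5. Zbtb32 apart, the genes were picked for small p on these same arrays. Their agreement among arrays follows largely from that choice and is no separate evidence. For Hgh1, Gxylt1, Rpp30 and Rbfa 1 array lay far from the others of its genotype.

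Of 31 gene lists, 11 passed limma's camera test with its preset correlation at an adjusted p under 0.05, 7 higher and 4 lower in Zbtb32-/- cells. None passed with an estimated correlation (smallest adjusted p = 0.79 with an estimated correlation), by limma's fry in either form, or by the exact permutation test of list means (smallest adjusted p = 0.559). Among the 11 lists the estimated correlation ran from 0.119 for NF-kB targets to 0.698 for immunoglobulin isotypes, against the preset 0.01. The preset test thus took their members as far less correlated than estimated. After quantile normalization was repeated the split became 5 higher and 8 lower, and after median centring 7 higher and 2 lower. Zbtb32-/- replicates 4 and 5 were left out together only after the data had been seen. Where both lay below all other arrays in a list, leaving them out raises the Zbtb32-/- mean of that list. The p-values of such lists without them are therefore no separate evidence. Without these 2 arrays 13 lists passed, 5 of them among the 11. Of those 5, NK cell markers turned from lower (-0.41) to higher (0.26). None of the lists passed with an estimated correlation (smallest adjusted p = 0.734 with an estimated correlation). No list member passed over all genes tested; adjusted over the list alone, Igha passed within the immunoglobulin isotypes (limma adjusted p = 0.00834) and no other member of any list did. For the B cell identity, germinal centre, mitochondrial ribosome, mitochondrial biogenesis, platelet and Zbtb32-neighbour lists, none of which passed on all arrays, the mean, the median and the test did not share a sign.

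**Figure D2:**
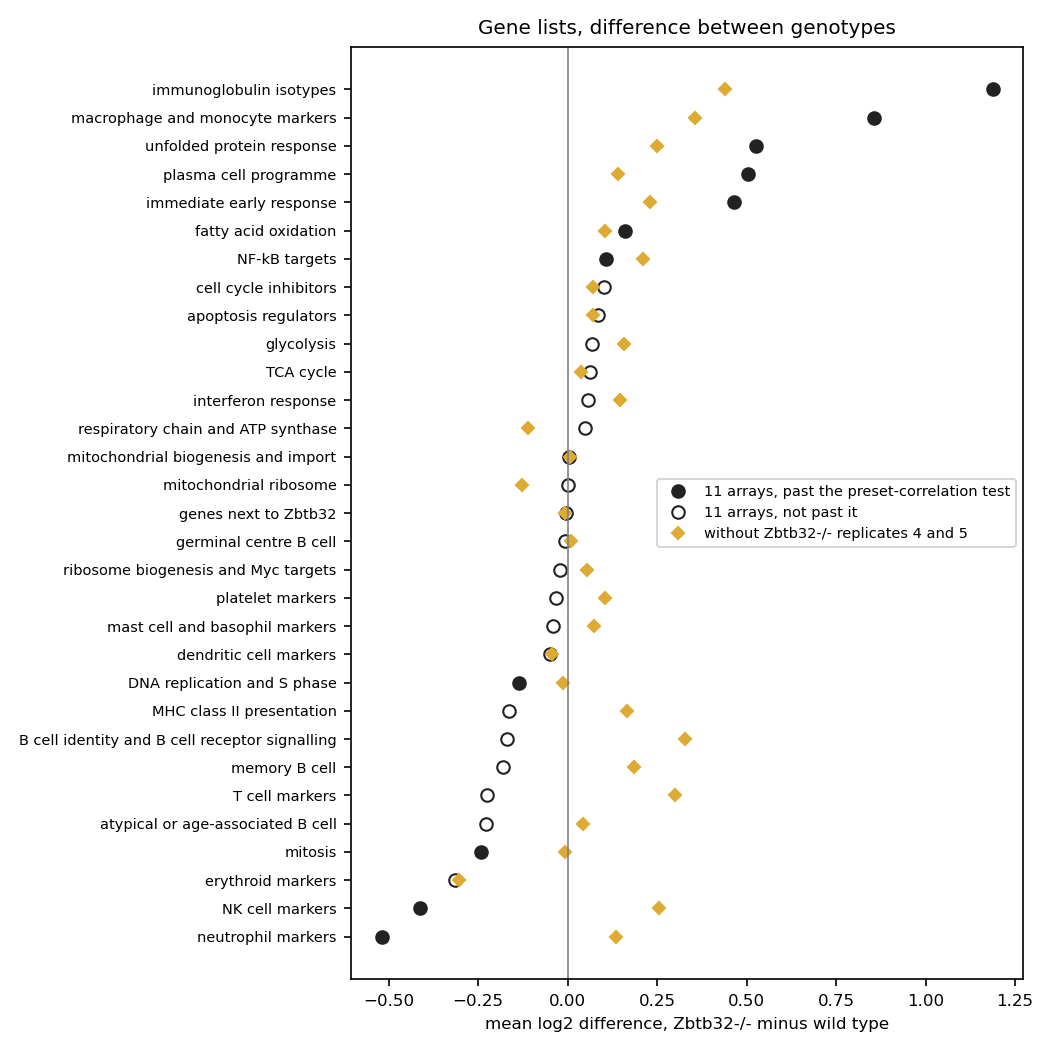
Mean log2 difference, Zbtb32-/- minus wild type (horizontal axis), of 31 gene lists (vertical axis); circles use 11 arrays, filled where the list passed the test with a preset correlation, and diamonds leave out Zbtb32-/- replicates 4 and 5. The 11 filled circles run from -0.52 for neutrophil markers to 1.19 for immunoglobulin isotypes.

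Cell cycle genes had slightly lower means in Zbtb32-/- cells. Of 39 measured mitosis genes 36 were lower, with a mean difference of -0.24, and the list passed the preset-correlation test (camera adjusted p = 0.000547) and not the other (adjusted p = 0.863 with an estimated correlation). Among its members Kif23, a kinesin of cell division, stood at -0.44 ± 0.16 (SE), Prc1, which bundles spindle microtubules, at -0.56 ± 0.22 and Cep55 at -0.81 ± 0.41. Of 44 DNA replication and S phase genes 33 were lower, with a mean of -0.13 (camera adjusted p = 0.0355; adjusted p = 0.938 with an estimated correlation). They included Orc6 of the origin recognition complex at -0.85 ± 0.28 and the histone chaperone subunit Chaf1b at -0.57 ± 0.28. List means lay below the wild type mean in 3 of 5 Zbtb32-/- arrays for both lists, and the mitosis mean ranged from 7.05 to 8.58 among the wild type arrays. Without Zbtb32-/- replicates 4 and 5 the differences were -0.0072 for mitosis and -0.012 for DNA replication, and neither list passed. Leaving out wild type replicate 1 or 5, or Zbtb32-/- replicate 3 or 4, also ended both calls, with mitosis differences between -0.10 and -0.14. DNA replication was also lost without wild type replicate 2 (-0.081) or Zbtb32-/- replicate 5 (-0.12) and with median centring (-0.14), and array weights gave -0.036 for mitosis and 0.017 for DNA replication, neither past. The 17 cell cycle inhibitors had a mean difference of 0.10 and did not pass (camera adjusted p = 0.255); without wild type replicate 6 it was 0.035 and without wild type replicate 1 it was 0.17.

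Mitochondrial genes showed no difference that passed in the comparison of all arrays. The 72 measured genes of the respiratory chain and ATP synthase averaged 10.29 ± 0.27 (SD, n = 6) in wild type and 10.34 ± 0.29 (SD, n = 5) in Zbtb32-/- cells, a mean difference of 0.05 (camera adjusted p = 0.393). The ATP synthase subunit Atp5d stood at 0.36 ± 0.19 (SE), cytochrome c1 (Cyc1) at 0.46 ± 0.32 and Ndufab1 of complex I at -0.23 ± 0.14. Cyc1 stood at 0.27 without wild type replicate 3, and Ndufab1 at -0.11 without Zbtb32-/- replicate 3. The 72 mitochondrial ribosomal genes averaged 8.57 ± 0.27 (SD, n = 6) and 8.57 ± 0.24 (SD, n = 5), with 29 higher and 43 lower (camera adjusted p = 0.818). Mrpl32 stood at -0.67 ± 0.23 (SE), Mrps6 at -0.39 ± 0.16 and Mrps27 at 0.75 ± 0.27, the last with wild type replicate 1 far above the other wild type arrays. Repeated quantile normalization turned both lists lower, at -0.065 and -0.091 (camera adjusted p = 0.00926 for each). The respiratory chain passed as higher without wild type replicate 1 (0.099) or 5 (0.11) or Zbtb32-/- replicate 3 (0.16), and the mitochondrial ribosome as lower without wild type replicate 6 (-0.074). In Zbtb32-/- replicates 4 and 5 the mean of the respiratory chain list was 0.40 above that in replicates 1 to 3, and that of the mitochondrial ribosome list 0.32 above. Without those 2 arrays the differences were -0.11 for the respiratory chain and -0.13 for the mitochondrial ribosome, both past the preset-correlation test (camera adjusted p = 0.00207 and 0.00344) and neither past it with an estimated correlation (adjusted p at least 0.734 with an estimated correlation).

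Other metabolic lists were close between the genotypes. Fatty acid oxidation passed the preset-correlation test with a mean of 0.16 and 14 of 19 genes higher (camera adjusted p = 0.0319; adjusted p = 0.79 with an estimated correlation). Its members included Acaa2 at 0.58 ± 0.24 (SE), for which Zbtb32-/- replicate 4 lay far above the rest. Cpt2, which passes fatty acyl groups from carnitine to coenzyme A inside mitochondria, stood at 0.69 ± 0.30. The call was lost after repeated quantile normalization (0.092, camera adjusted p = 0.18) and among brighter genes, those above the median signal (0.17, 0.191). It was also lost without wild type replicate 3 (0.10), 4 (0.14) or 6 (0.10) or Zbtb32-/- replicate 1 (0.15), 2 (0.15) or 4 (0.12). Mean differences that did not pass were 0.06 for 16 TCA cycle genes (camera adjusted p = 0.871), 0.07 for 18 glycolysis genes (0.507), -0.02 for 31 genes of ribosome biogenesis and Myc targets (0.327) and 0.00 for 35 genes of mitochondrial biogenesis and import (0.987). Glycolysis stood at 0.0088 without wild type replicate 6 and at 0.14 without wild type replicate 1. Without Zbtb32-/- replicates 4 and 5 it stood at 0.16 (camera adjusted p = 0.0414; adjusted p at least 0.734 with an estimated correlation), and fatty acid oxidation, at 0.10, did not pass. In the ribosome biogenesis list Wdr74 stood at 0.80 ± 0.23 and the nucleolar protein Npm1 at -0.56 ± 0.22. That list passed as lower after repeated quantile normalization (-0.10, camera adjusted p = 0.0299) and without wild type replicate 3 (-0.089) or 6 (-0.12) or Zbtb32-/- replicate 2 (-0.085).

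Genes of B cell identity, the memory state and antigen presentation differed among the Zbtb32-/- arrays more than between the genotypes. The 24 B cell identity and receptor signalling genes averaged 9.70 ± 0.25 (SD, n = 6) and 9.53 ± 0.70 (SD, n = 5), a mean difference of -0.17 (camera adjusted p = 0.898). That mean was 1.24 lower in Zbtb32-/- replicates 4 and 5 than in replicates 1 to 3. Without both arrays the difference was 0.33, past the preset-correlation test (camera adjusted p = 1.06e-06) and not with an estimated correlation (adjusted p at least 0.734 with an estimated correlation). Both arrays had the lowest means of this list and of the memory and MHC class II lists, and were left out after the data had been seen. Leaving them out raises these means, so the p-values without them are no separate evidence. Fcrla, an intracellular Fc receptor-like protein of B cells, stood at 0.58 ± 0.19 (SE). MHC class II presentation, 10 genes, had a mean difference of -0.16 (camera adjusted p = 0.542). The invariant chain Cd74 stood at 0.19 ± 0.11, the protease Ctss at 0.37 ± 0.16 and H2-Oa, a chain of the H2-O peptide exchange inhibitor, at -0.93 ± 0.55. H2-Oa stood at -0.48 without Zbtb32-/- replicate 5 and Ctss at 0.22 without replicate 4. Without replicates 4 and 5 the list stood at 0.17 (camera adjusted p = 0.018; adjusted p at least 0.734 with an estimated correlation). The 20 memory B cell genes stood at -0.18 (camera adjusted p = 0.256) and at 0.19 without the 2 arrays (camera adjusted p = 0.00473; adjusted p at least 0.734 with an estimated correlation). The memory list passed as lower among brighter genes (-0.19, camera adjusted p = 0.02) and without wild type replicate 6 (-0.23) or Zbtb32-/- replicate 2 (-0.32) or 3 (-0.30), so its direction depended on the arrays and genes kept. MHC class II passed as lower without Zbtb32-/- replicate 2 (-0.30). The 14 atypical or age-associated B cell genes at -0.23 (camera adjusted p = 0.0525) and the 19 germinal centre genes at -0.01 (0.679) did not pass. The atypical list passed as lower after repeated quantile normalization (-0.31, camera adjusted p = 0.00926), among brighter genes (-0.25, 0.00157) and without genes whose probe sets disagree (-0.24, 0.0478). It also passed without wild type replicate 3 (-0.22) or 6 (-0.25) or Zbtb32-/- replicate 1 (-0.26), 2 (-0.31) or 3 (-0.32), and stood at 0.042 without Zbtb32-/- replicates 4 and 5.

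The genes of the sort gate gave a check of the cells. Cd80, selected as present, averaged 9.27 ± 0.24 (SD, n = 6) in wild type and 8.38 ± 1.22 (SD, n = 5) in Zbtb32-/- cells, a difference of -0.89 ± 0.45 (SE), and Ccr6, also selected as present, averaged 7.07 ± 0.69 and 7.08 ± 1.37. In Zbtb32-/- replicates 4 and 5 Cd80 stood at 6.89 and 7.50 and Ccr6 at 5.85 and 5.69, below the lowest of the other 9 arrays, 8.40 for Cd80 and 6.38 for Ccr6. The differences of Itgam (CD11b) at -0.39 ± 0.54, Ly6g at 0.14 ± 0.38, Kit (CD117) at -0.01 ± 0.25, Ptprc (CD45) at -0.03 ± 0.26 and Ighm at 0.31 ± 0.19 did not pass. In replicates 4 and 5 Itgam stood at 6.87 and 6.52 and Ptprc at 10.70 and 10.29, below the lowest of the other arrays, 7.64 and 10.78. Ighm, whose protein was selected as absent, stood at 10.51 and 10.02 in them, above the highest of the others, 9.75. Without replicate 4 Cd80 stood at -0.52 and Ighm at 0.14. Ccr6 in wild type replicate 2 and Ly6g in Zbtb32-/- replicate 3 lay far above the other arrays of their genotype. Cd19 and Ighd were not analysed here.

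Genes of antibody secretion had higher means in Zbtb32-/- cells. All of the 22 unfolded protein response genes were higher, with a mean difference of 0.53 (camera adjusted p = 6.05e-08; adjusted p = 0.79 with an estimated correlation). Of 25 plasma cell genes 24 were higher, with a mean of 0.50 (camera adjusted p = 5.19e-06; adjusted p = 0.79 with an estimated correlation). Syvn1, a ubiquitin ligase of protein quality control in the endoplasmic reticulum, stood at 1.03 ± 0.43 (SE), Ppp1r15a at 1.10 ± 0.46, Derl3, which helps remove misfolded proteins, at 1.36 ± 0.66 and Glcci1 at 0.64 ± 0.29. Both lists lay above the wild type mean in 4 of 5 Zbtb32-/- arrays, and without Zbtb32-/- replicate 3 the plasma cell list stood at 0.78. Wild type replicate 1 had the highest mean of all arrays for both lists. It stood at 10.82 for plasma cell genes and at 10.94 for the unfolded protein response. The plasma cell list was 0.91 higher in Zbtb32-/- replicates 4 and 5 than in replicates 1 to 3, and without both arrays its difference was 0.14 and no longer passed. That of the unfolded protein response was 0.25 without replicates 4 and 5 (camera adjusted p = 0.018; adjusted p at least 0.734 with an estimated correlation). The 3 measured immunoglobulin isotype genes had a mean difference of 1.19 (camera adjusted p = 0.0112; adjusted p = 0.79 with an estimated correlation), made up of Igha at 3.00, Ighm at 0.31 and Ighg3 at 0.26 ± 0.52. The call was lost with array weights (1.03, camera adjusted p = 0.0888) and without Zbtb32-/- replicate 4 (0.80). Igha stood at 13.19 and 13.08 in Zbtb32-/- replicates 4 and 5, at 12.62 in replicate 2 and at 7.40 to 9.41 in the other 8 arrays. Without replicates 4 and 5 the list stood at 0.44 and did not pass.

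Among signalling lists, the immediate early response genes lay above the wild type mean in 5 of 5 Zbtb32-/- arrays, with a difference of 0.46 and 20 of 23 genes higher (camera adjusted p = 7.97e-08; adjusted p = 0.79 with an estimated correlation). The genotypes overlapped, with wild type replicate 1 at 8.23 above Zbtb32-/- replicates 1 to 3 at 8.12, 7.81 and 8.13. The list members Fos, Fosb and Egr1, transcription factors induced within minutes of a stimulus, stood at 1.12 ± 0.41 (SE), 1.33 ± 0.46 and 0.75 ± 0.23. Fosb in wild type replicate 1 lay far above the other wild type arrays. The list was 0.59 higher in Zbtb32-/- replicates 4 and 5 than in replicates 1 to 3, and without both it stood at 0.23 (camera adjusted p = 0.0089; adjusted p at least 0.734 with an estimated correlation). NF-kB targets had a mean difference of 0.11 with 13 of 19 higher (camera adjusted p = 0.0319; adjusted p = 0.79 with an estimated correlation), including Tnfaip3, an inhibitor of the pathway, at 0.50 ± 0.15 and Relb, one of its subunits, at 0.33 ± 0.11. The call was lost after repeated quantile normalization (0.038, camera adjusted p = 0.289) and among brighter genes (0.10, 0.314). It was also lost without wild type replicate 5 (0.068) or 6 (0.083) or Zbtb32-/- replicate 2 (0.042) or 3 (0.082). Without replicates 4 and 5 the difference was 0.21 (camera adjusted p = 0.000113; adjusted p at least 0.734 with an estimated correlation). The 24 interferon response genes, 14 higher and 10 lower, stood at 0.06 (camera adjusted p = 0.462), with Irf7 at 0.78 ± 0.23, and did not pass. The 24 apoptosis regulators at 0.08 (camera adjusted p = 0.169) did not pass either, but did without wild type replicate 1 (0.13). Without the 2 arrays the interferon list stood at 0.15 (camera adjusted p = 0.0136; adjusted p at least 0.734 with an estimated correlation).

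Markers of other cell types varied among the arrays. In the 9 arrays other than Zbtb32-/- replicates 4 and 5, the neutrophil marker S100a8 stood at 9.65 to 12.23. Itgam, whose protein was selected as absent, stood at 7.64 to 9.56 in them. Whether those 9 arrays held memory B cells alone was not tested. The 21 macrophage and monocyte genes had a mean difference of 0.86, with 19 higher and 5 of 5 Zbtb32-/- arrays above the wild type mean (camera adjusted p = 9.28e-12; adjusted p = 0.79 with an estimated correlation). The complement gene C1qa stood at 1.56 ± 0.51 (SE), the growth factor receptor Csf1r at 1.22 ± 0.40, the receptor kinase for dying cells Mertk at 1.86 ± 0.52 and the Fc receptor Fcgr3 at 0.97 ± 0.36. Zbtb32-/- replicate 4 at 9.89 and replicate 5 at 8.93 had the highest list means, followed by wild type replicate 3 at 8.71. Without replicate 4 the difference was 0.55, and without replicates 4 and 5 it was 0.36 (camera adjusted p = 0.000579; adjusted p at least 0.734 with an estimated correlation). Neutrophil markers, 17 of 18 lower, stood at -0.52 (camera adjusted p = 0.00673; adjusted p = 0.79 with an estimated correlation) with S100a8 at -1.47 ± 0.83 and S100a9 at -1.29 ± 0.73. NK cell markers, 10 of 13 lower, stood at -0.41 (camera adjusted p = 0.0355; adjusted p = 0.824 with an estimated correlation) with Gzma at -0.999 ± 0.53 and Klra8 at -0.96 ± 0.44. Without Zbtb32-/- replicate 4 S100a8 stood at -0.75, S100a9 at -0.71 and Gzma at -0.64, and without replicate 5 Gzma stood at -0.63. Without both arrays these genes stood at -0.086, -0.032 and -0.033. The neutrophil call was lost with array weights (-0.37, camera adjusted p = 0.15) and without wild type replicate 4 (-0.45) or 6 (-0.32) or Zbtb32-/- replicate 4 (-0.26) or 5 (-0.29). The NK cell call was lost with array weights (-0.13, camera adjusted p = 0.797), with median centring (-0.42, 0.0715) and without wild type replicate 1 (-0.34) or 4 (-0.34) or Zbtb32-/- replicate 4 (-0.18) or 5 (-0.15). Without replicates 4 and 5 these turned to 0.14 for neutrophils, which did not pass, and 0.26 for NK cells (camera adjusted p = 0.0414; adjusted p at least 0.734 with an estimated correlation). The 18 T cell markers stood at -0.22 (camera adjusted p = 0.273), with Ctla4 at 0.98 ± 0.31, and at 0.30 without the 2 arrays (camera adjusted p = 9.98e-05; adjusted p at least 0.734 with an estimated correlation). Both arrays had the lowest T cell and NK cell means, so the higher values without them follow in part from leaving them out. T cell markers passed as lower among brighter genes (-0.36, camera adjusted p = 0.00201) and without Zbtb32-/- replicate 1 (-0.38) or 2 (-0.37). Erythroid markers, with Car1 at -1.92 ± 0.79, stood at -0.32 (camera adjusted p = 0.0758), mast cell and basophil markers at -0.04 (0.635), dendritic cell markers at -0.05 (0.898) and platelet markers at -0.03 (0.94), none of which passed. The erythroid list passed as lower without wild type replicate 2 (-0.38), 3 (-0.38) or 4 (-0.40) or Zbtb32-/- replicate 5 (-0.35), and fell to -0.095 without wild type replicate 5 (camera adjusted p = 0.733), whose list mean lay far above the other wild type arrays.

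**Figure D3:**
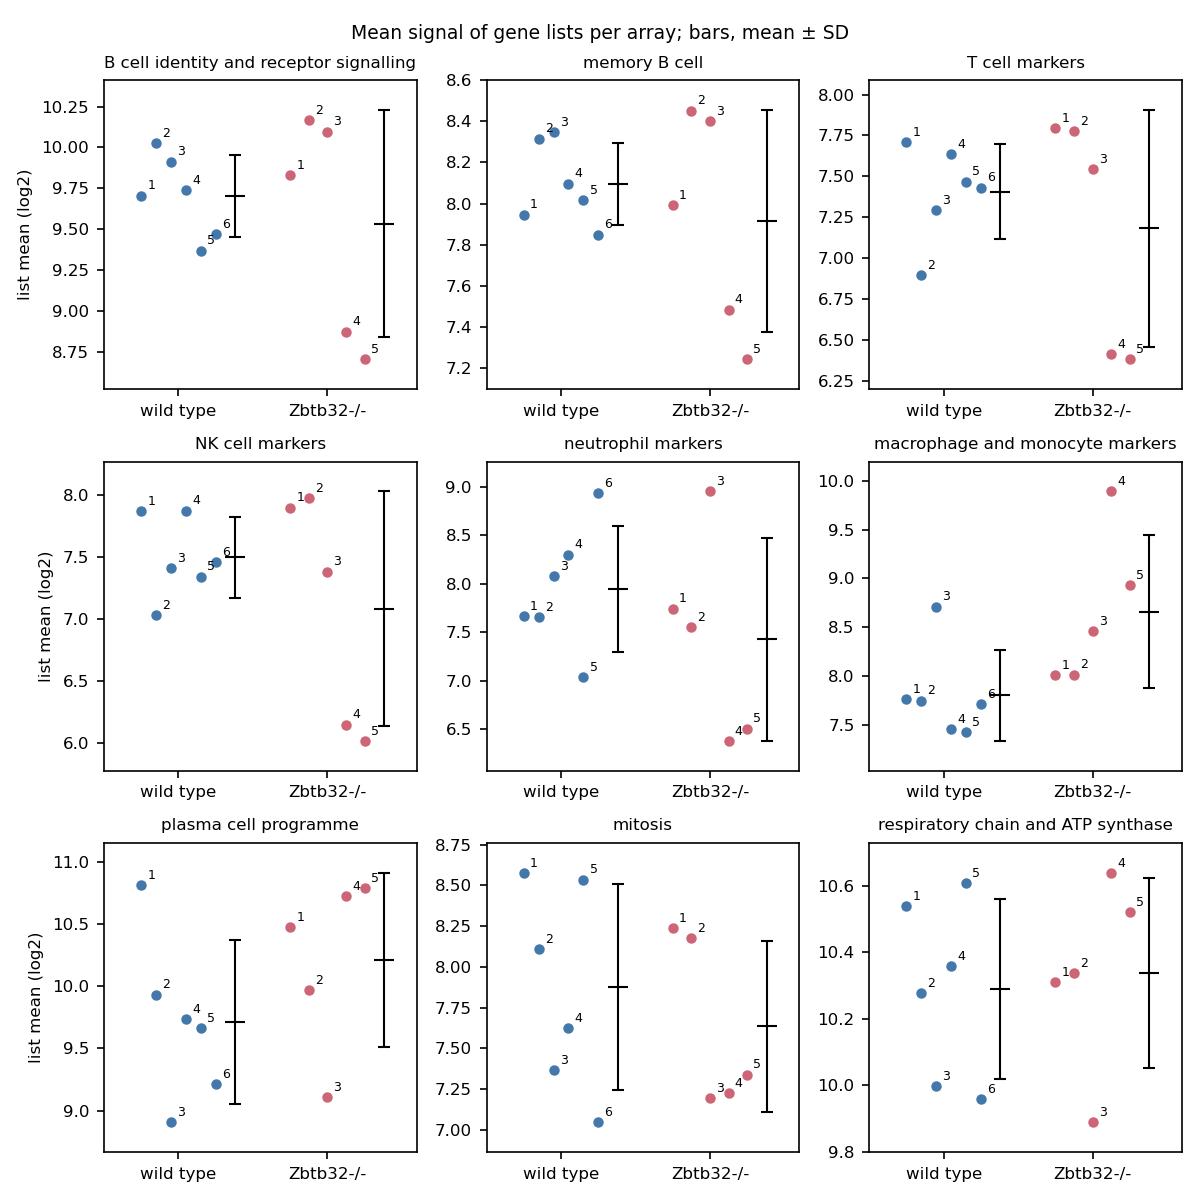
Mean log2 signal of 9 gene lists (vertical axes, each with its own range) in 6 wild type and 5 Zbtb32-/- arrays; points are arrays with their replicate numbers and bars give mean ± SD. Zbtb32-/- replicates 4 and 5 lie lowest for B cell identity, memory B cell, T cell, NK cell and neutrophil genes and highest for macrophage genes.

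The 39 measured genes of the hand-made list around Zbtb32 on its chromosome, where a knockout strain can carry donor sequence, had a mean difference of 0.00 (camera adjusted p = 0.898), with 20 higher and 19 lower.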

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

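Every test in this part was chosen after the values it weighs had been seen. Over 204 groups of values 11 had 1 array far from the rest of its genotype, against 10.2 expected by chance. Many genes behind these groups were picked for small p on these same arrays, so 10.2 is only a rough guide. The rule looks for 1 array apart from the others, so arrays that deviate together can hide each other. The count of flags therefore cannot decide whether arrays deviated more than chance brings.

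The list means concerned were macrophage and monocyte markers, 8.71 in wild type replicate 3 against 7.43 to 7.76 in the other wild type arrays, and erythroid markers, 7.54 in wild type replicate 5 against 6.03 to 6.54. Among genes with a high array, Fosb stood at 10.53 and Mrps27 at 6.93 in wild type replicate 1, Ccr6 at 8.35 in wild type replicate 2, Rbfa at 8.73 in Zbtb32-/- replicate 2, Ly6g at 7.09 in replicate 3, Acaa2 at 9.43 in replicate 4 and Gxylt1 at 7.54 in replicate 5. Low arrays were Hgh1 at 6.00 in wild type replicate 6 and Rpp30 at 7.05 in wild type replicate 2.

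Zbtb32-/- replicates 4 and 5 lay below or above all of the other 9 arrays in 1932 genes, the rank of this pair being 4 among 55 pairs, with Cd22 at a mean of 7.77 against 10.46 to 11.44 and Cr2 at 6.86 against 8.89 to 9.97. Scaling is argued against, since the B cell identity list stayed -1.28 log2 units lower in them than in replicates 1 to 3 after repeated quantile normalization, and so is a lower share of memory B cells with other cells in their usual proportions, since the T cell, NK cell and neutrophil lists were lower too, the smallest change being -1.31, while the macrophage list was higher. Genotype as the whole cause was not decided. The B cell identity list of replicates 1 to 3 lay 0.33 above the wild type mean. But replicates 4 and 5 were set apart after their low values in this list were seen, which raises the mean of the rest. A part played by genotype stays open and untested as well. Wild type memory B cells under a wrong genotype label are argued against by Zbtb32, which was lowest of all arrays in these 2, at 7.03 and 7.26, the nearer at -1.02 from the lowest wild type array. Another sorted population stays open as a candidate explanation, of either genotype if its cells hold little Zbtb32: Cd80 and Ccr6, for which the cells were gated, were lowest of all arrays in both, the smaller gap being -0.53 log2 units. The plasma cell list stood at 10.73 and 10.79 in replicates 4 and 5, near the 10.82 of wild type replicate 1. Whether plasma cells made up a part of these 2 arrays was not tested.

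The macrophage list was higher in Zbtb32-/- cells, and 16 of its 21 members lay above all other arrays in replicates 4 and 5, among them Spic, a regulator of red pulp macrophages, while the gate excluded CD11b. Replicates 4 and 5 as the whole cause cannot be told apart from a smaller shift shared by the genotype, since without them the mean difference was 0.36. That difference still passed at the preset correlation (camera adjusted p = 0.000579), the list failed with an estimated correlation both with and without them, and wild type replicate 3 lay above each of Zbtb32-/- replicates 1 to 3. Macrophages of one kind present in varying amounts stay open as well: Lyz2, the brightest member in wild type arrays, was lower in replicates 4 and 5 than in replicates 1 to 3, at -1.63 log2 units, but neutrophils also hold this transcript and their markers were lower too.

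Zbtb32 in wild type replicate 1, at 8.28, lay nearer to the Zbtb32-/- arrays than to the other wild type arrays. A swap with a Zbtb32-/- array is argued against, since the highest of those lay at -1.38 log2 units from the lowest of wild type replicates 2 to 6, so that no partner was out of place. This array also had high Sdc1 (10.82) and Prdm1 (9.76), genes of plasma cells, and over the 6 wild type arrays Zbtb32 and the plasma cell list had r = -0.80 (exact permutation p = 0.0583; Spearman's rho = -0.60, exact permutation p = 0.242), the 1 relation tested. Without wild type replicates 1 and 3, which lay farthest from the median of the list, r was 0.057. Leaving out the extremes narrows the range of the list and leaves few arrays, so this value decides nothing. With the exact permutation p = 0.0583 over 6 arrays, dilution as a part of the cause cannot be told apart from a spread of Zbtb32 among memory B cells. Dilution as the whole cause is argued against: Zbtb32 was -1.72 from the mean of the other wild type arrays, while 10 B cell genes silenced in plasma cells had a median change of -0.51 (SD 0.37) and no B cell identity member fell below -1.06. This holds only if the plasma cells present had silenced those 10 genes as fully as Zbtb32, which was not tested.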

How the results depend on the processing

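Leaving out Zbtb32-/- replicates 4 and 5 together was chosen after the data had been seen; every other alternative was fixed before. The difference of Zbtb32 kept its direction and an unadjusted p under 0.05 under every alternative that was run, from -2.50 to -1.98. No gene passed under any alternative except without wild type replicate 1, where 3 did: the range over single left-out arrays was 0 to 3. At an unadjusted p under 0.05 the count of 673 became 1733 with array weights, 1176 over every probe set, 414 among brighter genes (those above the median signal), where fewer genes were tested, 549 with the unmoderated test, and 460 to 1892 with single arrays left out. Of 70 other named genes in 1323 gene and setting pairs, 1295 kept their sign and 0 passed the adjusted threshold. Of 71 named genes 15 moved by over 1.5 times or turned with 1 array left out, and 32 without Zbtb32-/- replicates 4 and 5. The 20 measured genes on each side of Zbtb32 in the reference table did not pass either.

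The count of 11 lists went to 6 with array weights, to 0 with an estimated correlation, 0 with fry, 0 with fry for either direction and 0 by exact permutation, and to 5 to 14 with single arrays left out, lowest without Zbtb32-/- replicate 4. Under these 4 set tests mitosis at -0.24 and DNA replication at -0.13 no longer passed; with array weights mitosis stood at -0.036, and with median centring DNA replication stood at -0.14, neither passing. The estimated correlation between genes was 0.659 for mitosis and 0.434 for DNA replication, against the preset 0.01. A higher correlation makes the p of camera larger. For the other changes, here and in what follows, the cause was not tested. Array weights also ended the calls of immunoglobulin isotypes at 1.03, neutrophil markers at -0.37 and NK cell markers at -0.13, and median centring that of NK cell markers at -0.42. Repeated quantile normalization ended those of NF-kB targets at 0.038 and fatty acid oxidation at 0.092, and ribosome biogenesis at -0.10 and atypical B cell at -0.31 passed as lower. Among brighter genes NF-kB targets at 0.10 and fatty acid oxidation at 0.17 no longer passed, while T cell markers at -0.36, atypical B cell at -0.25 and memory B cell at -0.19 passed as lower. Atypical B cell also passed, at -0.24, without genes whose probe sets disagree.

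These differences turned sign. Repeated quantile normalization gave -0.065 for the respiratory chain and -0.091 for the mitochondrial ribosome (camera adjusted p = 0.00926 for both), -0.054 for mitochondrial biogenesis, -0.030 for the TCA cycle and -0.0018 for interferon response. Median centring gave -0.0056 for the mitochondrial ribosome and -0.0013 for mitochondrial biogenesis. Among brighter genes, where fewer members were tested, values were -0.010 for the mitochondrial ribosome, -0.0015 for mitochondrial biogenesis, 0.13 for germinal centre and 0.060 for mast cell markers. Array weights gave 0.017 for DNA replication, -0.061 for the mitochondrial ribosome, 0.048 for ribosome biogenesis, 0.0012 for germinal centre, 0.064 for Ptprc and 0.077 for Kit.

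With the replicate number as a replicate block, for numbers 1 to 5 and so without wild type replicate 6, 0 genes and 12 lists passed and 879 genes had an unadjusted p under 0.05. This fit has the same differences as the one that only leaves out that array, where 12 lists and 572 genes passed those thresholds, so no change of sign comes from the block. Of the 4 lists gained, all lower and all past without that array alone, the mitochondrial ribosome stood at -0.074 (camera adjusted p = 0.00274), ribosome biogenesis at -0.12 (0.00183), atypical B cell at -0.25 (0.0152) and memory B cell at -0.23 (0.0454). The 3 not called were fatty acid oxidation at 0.10 (0.284) and NF-kB targets at 0.083 (0.177), which did not pass without that array alone either, and the NK cell markers list at -0.42 (0.0813), which did (0.0273). The neutrophil markers list at -0.32 passed with the block (0.0359) and not without that array alone (0.0516). Values that turned were -0.017 for the respiratory chain, -0.074 for the mitochondrial ribosome, -0.068 for mitochondrial biogenesis, -0.012 for the TCA cycle, 0.00042 for platelet markers, -0.066 for Ccr6 and 0.029 for Kit. Deviations of same-numbered arrays from their group means correlated at 0.262, 0.257, 0.333, 0.0171 and 0.116 for numbers 1 to 5. Every pair had to exceed 0.1 for the numbers to be taken as pairs, and number 4 did not. Arrays numbered 1 to 3 correlated best with their own number in both directions, while those numbered 4 and 5 did not all do so. A link by number for 1 to 3 therefore stays open.

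Without Zbtb32-/- replicates 4 and 5 mitosis stood at -0.0072 and DNA replication at -0.012, neither passing. Signs turned for the respiratory chain at -0.11, the mitochondrial ribosome at -0.13, ribosome biogenesis at 0.054, germinal centre at 0.0090, memory B cell at 0.19, atypical B cell at 0.042, B cell identity at 0.33, MHC class II at 0.17, T cell markers at 0.30, NK cell markers at 0.26, neutrophil markers at 0.14, mast cell markers at 0.073, platelet markers at 0.10, H2-Oa at 0.021, Itgam at 0.55, Ighg3 at -0.57, Ptprc at 0.42 and Kit at 0.24.

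With 1 array left out at a time the differences ranged from -0.41 to -0.10 for mitosis, -0.23 to -0.028 for DNA replication, -0.026 to 0.16 for the respiratory chain, -0.074 to 0.091 for the mitochondrial ribosome, -0.30 to 0.018 for MHC class II, -0.12 to 0.060 for ribosome biogenesis, -0.038 to 0.028 for germinal centre, -0.028 to 0.018 for genes next to Zbtb32, -0.068 to 0.052 for mitochondrial biogenesis, -0.012 to 0.16 for the TCA cycle, -0.33 to 0.038 for B cell identity, -0.15 to 0.085 for platelet markers and -0.085 to 0.042 for mast cell markers. Further ranges were 0.042 to 0.17 for NF-kB targets, 0.10 to 0.25 for fatty acid oxidation, -0.64 to -0.15 for NK cell markers, -0.90 to -0.26 for neutrophil markers, -0.32 to -0.11 for atypical B cell, -0.32 to -0.013 for memory B cell and -0.38 to -0.024 for T cell markers; the results name the arrays whose absence changed each of these calls. The remaining lists ranged from 0.0088 to 0.14 for glycolysis, 0.035 to 0.17 for cell cycle inhibitors, 0.011 to 0.12 for interferon response, 0.048 to 0.13 for apoptosis regulators, -0.11 to -0.012 for dendritic cell markers, -0.40 to -0.095 for erythroid markers, 0.55 to 1.04 for macrophage markers, 0.34 to 0.78 for the plasma cell programme, 0.40 to 0.75 for the unfolded protein response, 0.36 to 0.58 for immediate early response and 0.80 to 1.53 for immunoglobulin isotypes. The ranges of single genes were -0.34 to 0.36 for Ccr6, -0.16 to 0.15 for Kit, -0.19 to 0.19 for Ptprc, -0.18 to 0.38 for Ly6g, -0.29 to 0.51 for Ighg3 and -0.75 to 0.0049 for Itgam. Mitosis no longer passed without wild type replicate 1 or 5 or Zbtb32-/- replicate 3 or 4, and DNA replication without those or without wild type replicate 2 or Zbtb32-/- replicate 5. The respiratory chain passed as higher without wild type replicate 1 at 0.099, wild type replicate 5 at 0.11 and Zbtb32-/- replicate 3 at 0.16, and the mitochondrial ribosome as lower without wild type replicate 6 at -0.074. MHC class II passed as lower without Zbtb32-/- replicate 2 at -0.30.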

Other observations

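The test of splits for gene lists was fixed before its result was seen, and those for genes were written afterwards. Among 100 splits of the 11 arrays into 6 and 5, the real one included, the highest count of genes past the adjusted threshold was 7 outside the real split. A real count of 0 is reached by each of the 100 by construction, so nothing follows for that count. For genes at an unadjusted p under 0.05, 48 of the splits gave as many as the real 673, with 3988 as the highest other count, and for gene lists 63 gave as many as the real 11, with 21 as the highest. Chance is thus not excluded for the count of genes at an unadjusted p under 0.05 or for the count of lists. Splits that call several times the real count point to a structure of the samples other than genotype.

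The 11 arrays differed along axes that the labels do not name. The first principal component held 29.7% of the variance and the second 20.5%, with Zbtb32-/- replicates 4 and 5 at -42.89 and -34.76 on the second. Wild type replicate 1 and Zbtb32-/- replicate 2 formed the pair with the most genes outside the other 9 arrays, 2825, against a median of 454 over 55 pairs.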
